A study of Mus musculus with 6 samples.

How the data were processed

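RNA of whole adrenal glands from 6 female mice, 3 control and 3 mutant animals aged 2 months, was measured on Affymetrix whole-transcript arrays, 1 array per animal. Per the labels' protocols, total RNA was prepared with a silica column kit from frozen glands, copied into sense-strand cDNA, fragmented and end-labelled. Groups were taken from the sample descriptions and genotypes in the labels, which name the animals separately, so the replicates are different animals. Groups share replicate numbers in the labels.

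The deposited values are log2 signals per probe set, with 1 column per animal, and the log2 scale was read from their range. The submitters' processing notes name Transcriptome Analysis Console 4.0. Background correction, summarisation and the normalization between arrays are not given in the sources used here. Any step that forces arrays to a common distribution would hide a shift shared by most genes, and log2 signals from arrays compress differences at the dim and at the bright end. Median log2 signals of the 6 arrays, from 6.76 to 6.83, were close together, so the values were used without further normalization. Detection calls were not used here. The range of the 23 background probe sets, 2.53 to 7.32, serves as a guide to which genes were dim, and precision is limited by the number of animals.

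Control probe sets were left out before testing: 5222 for introns, 1324 for exons and 94 spike or background probe sets, 6640 in all. This left 22206 probe sets. A table of the platform's annotation gave 1 gene symbol to 19572 of these, several to 0 and none to 2634, which are unnamed here. All 19572 named probe sets matched an Entrez identifier in the NCBI gene table of assembly GRCm38.p6, which changed 0 symbols, and they cover 19505 genes. No genome build is named in the sources used here, so no coordinates are given. As a sign of RNA quality, the mean signal of the intron control probe sets was 5.47, 5.40 and 5.84 in the controls and 5.73, 5.45 and 5.71 in the mutants.

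Mutant minus control was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 6 arrays without covariates or a filter on dim probe sets. P-values are two-sided and adjusted by Benjamini-Hochberg over the 22206 probe sets, with a threshold of 0.05. An SE or 95% interval given for a gene belongs to the limma fit, with the moderated variance. The SEs of changes in list means, given under other observations, come from the animals' list means without moderation. Folds are powers of 2 of the log2 change.

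Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. A gene was represented by its probe set of highest mean, and the 25 lists with at least 3 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. The preset correlation is small, and where genes of a list vary together between animals it gives p-values that are too small. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were therefore run beside it. The lists share some genes, such as Shh, Lats2, Hsd3b6 and Ccn1, so their tests are not independent. Members were also counted with adjustment over the list alone. List means per animal were compared by an exact two-sided permutation test, whose smallest p is 0.1 with 3 animals against 3.

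The rule for named genes took Stk4 and Stk3, the 12 largest rises and 12 largest falls among probe sets past the threshold whose groups did not overlap, and up to 4 genes of smallest unadjusted p from each list. Where fewer than 12 passed, the places were filled by smallest unadjusted p among changes of at least 1.5-fold that separated the groups. Cyp11b1, Cyp11b2, Star, Nr5a1, Ccn1, Ccn2, Gli1, Th and Akr1c18 were always included. Gli3 and Sox9 were named after their values were seen, to complete counts of members past the threshold adjusted over the list alone. So were the lower members of the YAP/TAZ target list, and Nr2f1, Nr2f2, Rspo1, Rspo3, Wt1 and Smo, to show list members that fell or changed little.

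The procedure was tested on simulated data with the real means and spread over 22206 probe sets. It called 39 of 100 probe sets changed by 1 log2 unit and 87 of 100 changed by 2, all with the right sign, with 8 false calls. A list shifted by 0.5 log2 units over 19505 simulated genes that varied independently had a camera adjusted p of 3.85e-10, and 0 other lists were called.

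Alternatives were quantile normalization, a shift of each array to a common median, only probe sets above the median level, only probe sets with 1 gene symbol, eBayes with trend and robust, array weights, the replicate number as a block, each animal left out in turn, other thresholds, and the mean of a gene's probe sets. Added after seeing the data were each array's intron control mean and its adipocyte list mean as covariates.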

Results

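Whole adrenal glands of 2-month-old female mice were profiled on Affymetrix whole-transcript arrays, 1 array per animal. Control mice (n = 3) carried floxed alleles of both genes for the Hippo pathway kinases MST1 and MST2. Mutant mice (n = 3) carried the same floxed alleles and the Nr5a1-Cre transgene, which is active in steroid-producing cells, so that both kinases were to be lost from the adrenal cortex. MST1 and MST2, encoded by Stk4 and Stk3, sit at the head of a kinase chain that restrains the coactivators YAP and TAZ. The comparison asked which transcripts differed between mutant and control glands. After removal of control probe sets, 22206 probe sets were compared, and their median log2 signal per array lay between 6.76 and 6.83. Arrays correlated at 0.9908 to 0.9933 within groups and at 0.988 to 0.9918 between groups, across probe sets, which are not independent replicates. The number of animals limits the precision of every value given.

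The targeted kinase Stk4 had a mean log2 signal of 8.64 ± 0.31 in control glands and 8.32 ± 0.16 in mutant glands (SD, n = 3 each; probe set TC0200002502.mm.2). Its log2 change of -0.32 (SE 0.19, 95% interval -0.77 to 0.12, limma adjusted p = 0.623) did not pass the test, and the animals of both groups overlapped. Stk3 was not analysed here. Where the Stk4 probes lie relative to the floxed exons is not given in the sources used here, and whole glands also hold cells without Cre, so this value does not check the genotype labels.

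In mutant glands 12 genes rose and 4 fell past an adjusted p of 0.05, all by at least 2-fold and each with the 3 mutants on one side of the 3 controls. Pianp, a membrane protein first described in neural tissue, rose a measured 15.6-fold, from 5.89 ± 0.32 to 9.85 ± 1.01 log2 units (SD, n = 3 each; limma adjusted p = 0.0296). Esrp2, a splicing regulator of epithelial cells, rose a measured 10.7-fold, from 6.46 ± 0.23 to 9.88 ± 0.17 (SD, n = 3 each; probe set TC0800002852.mm.2). With a log2 change of 3.43 (SE 0.18, limma adjusted p = 0.00072), Esrp2 had the smallest adjusted p of all probe sets. Sparcl1, a secreted matrix glycoprotein related to SPARC, rose 5.02-fold (log2 change 2.33, SE 0.24, limma adjusted p = 0.0223).

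Ajuba, a LIM-domain protein that binds LATS kinases, rose 3.75-fold, from 10.95 ± 0.06 to 12.86 ± 0.18 (SD, n = 3 each; limma adjusted p = 0.00878). Lrrc32, which holds latent TGF-beta at the cell surface, rose 3.86-fold (limma adjusted p = 0.0223), and the ligand gene Tgfb2 rose 2.70-fold (limma adjusted p = 0.0357). P4ha3, a subunit of collagen prolyl hydroxylase, rose 2.31-fold and had the largest adjusted p of the called genes (0.0498, limma). The remaining genes that rose did so by 2.59-fold to 3.46-fold, with limma adjusted p from 0.0223 to 0.0296. They were Speg, a kinase of striated muscle, Bcat1, which transaminates branched-chain amino acids, the serine protease family member Prss35, the Rab27 effector Sytl5, and Scrn1. Mean control signals of Pianp, Esrp2, Speg and Bcat1, and both group means of P4ha3, lay within the range of the array's background probe sets, 2.53 to 7.32, so these folds depend on a signal not told apart from background, may be too small, and give no order among these genes.

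The genes that fell include a transporter, a secreted peptide and a pair of lipid enzymes. Slc6a15, a transporter of neutral amino acids, fell 4.42-fold, from 8.92 ± 0.17 to 6.77 ± 0.22 (SD, n = 3 each; limma adjusted p = 0.00878), to a level within the background range. Pla2g2f, a secreted phospholipase A2, fell 3.44-fold (limma adjusted p = 0.0357). Ecrg4, which encodes the secreted peptide precursor augurin, fell 3.20-fold, and Chka, the choline kinase that starts phosphatidylcholine synthesis, fell 2.78-fold (limma adjusted p = 0.0223 for each). A further 8 lower genes were taken by smallest unadjusted p and did not pass the test, with limma adjusted p from 0.0529 to 0.0558. They include Nr0b1, a nuclear receptor that opposes Nr5a1 (log2 change -1.33, SE 0.19), the secreted WNT antagonist Frzb (-1.05, SE 0.13) and the collagen-binding integrin Itga2 (-2.16, SE 0.29). The others were Gulo, the last enzyme of vitamin C synthesis (-2.42, SE 0.34), Pla2g2d (-1.41), Sphkap (-1.33), Cdr2l (-1.30) and Cib4 (-1.25), with mutant means of Gulo, Sphkap and Cib4 within the background range.

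**Figure D1:**
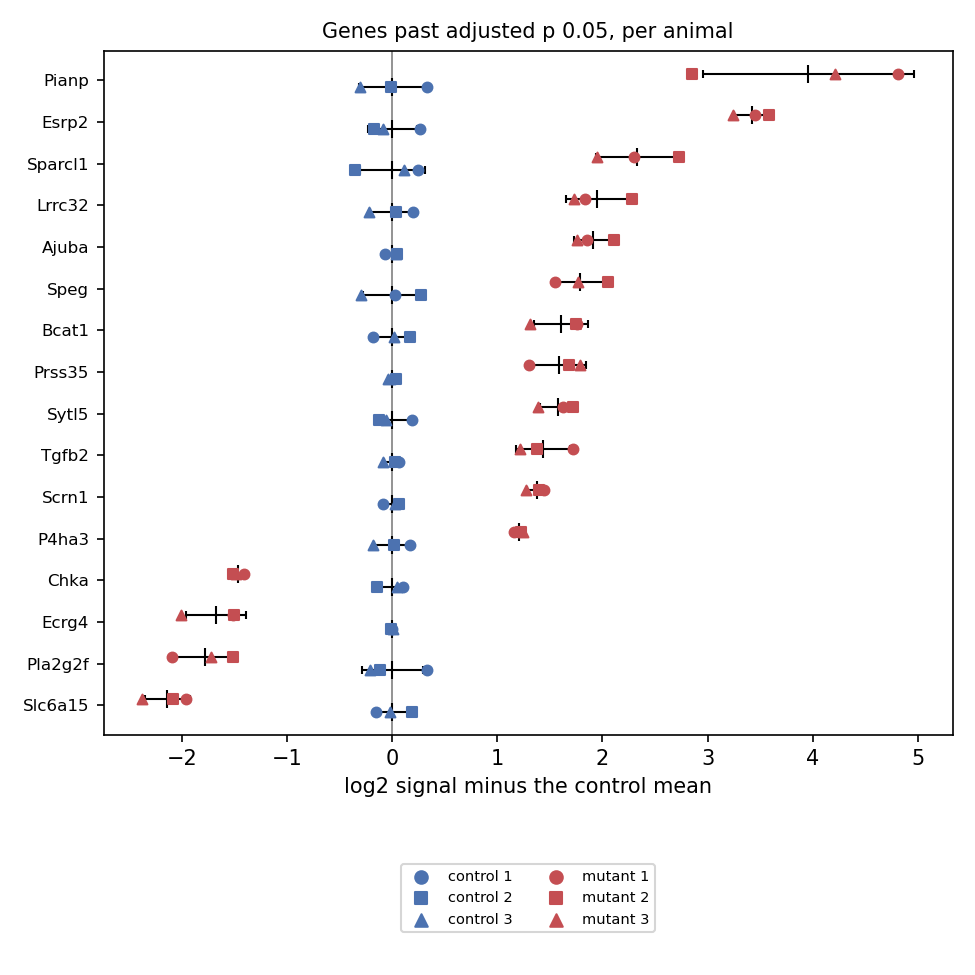
Log2 signal of the 16 genes past an adjusted p of 0.05, as each animal's value minus the control mean of that gene (x axis, log2 units; 1 gene per line), with controls in blue, mutants in red, a bar at each group mean and whiskers of 1 SD. For each of the 12 genes that rose and the 4 that fell, the 3 mutants lie on one side of the 3 controls.

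The test was limma's moderated test over 22206 probe sets with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 2306 probe sets, 1204 higher and 1102 lower, where chance alone would give 1110 on average. Other splits of the same 6 animals into 3 and 3 gave from 704 to 1530. The groups did not overlap for 3632 probe sets, or 16.4%, where chance gives 10%. The count of 16 depended on single animals: it was 1 (Esrp2) without control 1, without control 2 and without control 3, and 6 without mutant 2. With each array shifted to a common median it was 32, of which 20 were higher and 12 lower, against 12 and 4. It reached 175 when the variance was modelled with a trend on signal level and a robust prior together, and was 8 with each array's intron control signal as a covariate and 2 with its adipocyte signal as a covariate.

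YAP/TAZ target genes were higher in mutant glands as a list fixed in advance. Of its 24 measured members, 19 were higher, by a mean of 0.52 log2 units, and the list rose past the test (limma camera adjusted p = 5.93e-09). This call was lost with an estimated correlation between genes (adjusted p = 0.349), and was held by the fry test (adjusted p = 0.0381). Ajuba and Tgfb2 rose over all probe sets, 0 fell and 22 did not pass, whereas 12 were higher past the threshold adjusted over the list alone. Examples of these are Myof, a membrane repair protein (log2 change 1.22, SE 0.21), Crim1, a transmembrane regulator of bone morphogenetic proteins (0.87, SE 0.15), and the kinase Lats2 (0.61, SE 0.19). Ccn1 and Ccn2, widely used readouts of YAP activity, had log2 changes of 0.55 (SE 0.26, limma adjusted p = 0.523, and 0.24 without mutant 3) and 0.19 (SE 0.20, limma adjusted p = 0.797). The 5 lower members were Amotl2 (-0.32, SE 0.38), Fjx1 (-0.19), Foxf2 (-0.14), Ankrd1 (-0.13) and Nuak2 (-0.08). All but Amotl2 of these lay within the background range in both groups. List means were 8.92, 8.81 and 8.98 in the controls and 9.53, 9.34 and 9.40 in the mutants. Markers of other cell types were higher beside it, by a mean of 0.42 for fibroblast, 0.40 for smooth muscle and 0.32 for endothelial genes, and mutant 1 had the highest mean of the 6 animals in the YAP/TAZ, fibroblast, smooth muscle and adipocyte lists. The Hippo pathway list, which includes Stk4 itself and shares Lats2 with the target list, rose by a mean of 0.15 over 21 genes, 13 of them higher (limma camera adjusted p = 0.0255). With an estimated correlation its adjusted p = 0.414, and 0 members passed over all probe sets or adjusted over the list alone. Fat4, an atypical cadherin upstream of the kinases, had a log2 change of 0.75 (SE 0.21, limma adjusted p = 0.278). The pathway call was lost without control 1 (mean 0.12), control 2 (0.10) or mutant 1 (0.12), without dim probe sets (0.11) and with either covariate (0.12 with the intron signal, 0.11 with the adipocyte signal), and the mean was 0.22 without control 3.

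Steroid synthesis genes were lower in mutant glands as a list, with log2 changes below 0 for 12 of 15 measured members. The list fell past the test (mean change -0.24, median -0.11, limma camera adjusted p = 0.0208), and also in the fry test (adjusted p = 0.0418), but not with an estimated correlation (adjusted p = 0.414). Over all probe sets 0 members passed, and adjusted over the list alone 2 did, both lower: Nr0b1 and Hsd3b6, a hydroxysteroid dehydrogenase of the outer cortex (log2 change -1.003, SE 0.25). Changes of the remaining members were smaller, from -0.34 (Mrap) to 0.12 (Cyp11a1). Nr0b1 opposes Nr5a1 and is no enzyme of synthesis, so the list mean does not measure a fall of the enzymes. The enzymes that complete corticosterone and aldosterone synthesis did not pass. Cyp11b1 measured 18.64 ± 0.07 in control and 18.55 ± 0.10 in mutant glands, and Cyp11b2 13.40 ± 0.10 and 13.16 ± 0.32 (SD, n = 3 each; limma adjusted p = 0.871 and 0.724). Star, the cholesterol carrier of mitochondria, differed by -0.01 (SE 0.14), the master regulator Nr5a1 by -0.11 (SE 0.14) and Mrap, a partner of the ACTH receptor, by -0.34 (SE 0.15). Signals of Cyp11b1 and Star were high enough that saturation, which was not assessed, would shrink a difference. The steroid list's call was lost without control 3 (mean -0.23) and without mutant 1 (mean -0.21).

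Markers of the cortical zones did not pass as lists over the 6 animals. Of 14 zona glomerulosa markers 8 were lower (mean -0.17, and -0.085 without mutant 3, limma camera adjusted p = 0.25), and 3 passed adjusted over the list alone: Hsd3b6, the angiotensin receptor Agtr1b (log2 change -1.21, SE 0.27, mutant mean within the background range) and, in the other direction, the hedgehog ligand Shh (0.71, SE 0.21). Of 6 zona fasciculata markers 5 were lower (mean -0.16, limma camera adjusted p = 0.13; -0.11 without mutant 1, and -0.24, past the threshold, without mutant 3), among them the transporter Abcb1b (-0.40, SE 0.16), and 0 passed adjusted over the list alone. The X-zone is the innermost, fetal-type cortex of young female mice. Its 3 markers had a mean change of 0.01 and a median of -0.01 (limma camera adjusted p = 0.891), with Akr1c18, which inactivates progesterone, at 18.85 ± 0.06 and 18.83 ± 0.04 (SD, n = 3 each). Akr1c18 was as bright as the steroid enzymes above, and saturation would shrink a difference in it too. Cholesterol synthesis genes were lower in 14 of 16 cases without passing (mean -0.13, limma camera adjusted p = 0.154), Insig1 with a log2 change of -0.40 (SE 0.23) among them, and 0 passed adjusted over the list alone. The cholesterol list passed without control 3 (mean -0.27), without mutant 1 (-0.23) and with array weights, and its mean was 0.0089 without mutant 3.

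Genes of the capsule, the connective tissue shell of the gland, and of hedgehog signalling rose as a list. Their mean change was 0.44 over 15 genes, 13 of them higher (limma camera adjusted p = 0.000196, adjusted p = 0.414 with an estimated correlation). Over all probe sets 0 passed. Adjusted over the list alone 5 did, all higher: Shh, its receptor Ptch1 (log2 change 1.07, SE 0.28), Gli3, the coreceptor Gas1 (0.72, SE 0.20) and Tcf21, a transcription factor of capsular cells (1.46, SE 0.24, limma adjusted p = 0.0782). Gli1, a direct hedgehog target, measured 6.31 ± 0.46 and 6.93 ± 0.29 (SD, n = 3 each; limma adjusted p = 0.459), both within the background range. Of the members outside hedgehog signalling, Tcf21 apart, Rspo1, Wt1, Nr2f2 and Rspo3 had log2 changes from 0.07 to 0.26. Nr2f1 was lower (-0.37, SE 0.14), as was the hedgehog member Smo (-0.14, SE 0.17). List means were 9.04, 8.88 and 9.313 in controls and 9.58, 9.66 and 9.307 in mutants, so the groups overlapped. WNT target genes did not pass, with a mean change of 0.07, a median of -0.05 and 4 of 10 higher (limma camera adjusted p = 0.734). Axin2, a common WNT readout, had a log2 change of 0.30 (SE 0.17), and the WNT inhibitor Apcdd1 alone passed adjusted over the list alone (1.22, SE 0.26).

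Gonad-like genes, chosen as genes of ovarian or testicular somatic cells, also rose as a list. Over 12 measured genes, 10 of them higher, the mean change was 0.37 (limma camera adjusted p = 0.00307, adjusted p = 0.414 with an estimated correlation). Over all probe sets 0 passed, and adjusted over the list alone 4 were higher (Gata4, Inha, Foxl2 and Sox9) and Fshr was lower. Gata4, a transcription factor of gonadal cells, measured 6.47 ± 0.28 and 7.89 ± 0.47 (SD, n = 3 each; limma adjusted p = 0.0999), its control mean within the background range. Inha, the inhibin alpha subunit, measured 14.41 ± 0.06 and 15.00 ± 0.07 (SD, n = 3 each; limma adjusted p = 0.192). It was bright in control glands too, so its signal here does not mark gonadal cells. Of the 12 genes, 10 lay within the background range in both groups, Foxl2, Sox9 and Fshr among them, and the others were Gata4 and Inha. Without dim probe sets 3 genes were left, Gata4, Inha and Sox9, with a mean of 0.90.

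Stromal and vascular markers were higher in mutant glands on average. Fibroblast and matrix genes rose by a mean of 0.42, with 16 of 20 higher (limma camera adjusted p = 4.45e-05, adjusted p = 0.414 with an estimated correlation), although 0 passed over all probe sets or adjusted over the list alone. Fibroblast list means were 10.31, 10.10 and 10.54 in controls and 11.00, 10.77 and 10.45 in mutants, so mutant 3 lay below control 3. Fibronectin, Fn1, had a log2 change of 1.35 (SE 0.36), the collagen chain Col1a2 0.77 (SE 0.29) and the proteoglycan Lum 0.69 (SE 0.20). Endothelial genes rose by a mean of 0.32, with 11 of 13 higher (limma camera adjusted p = 9.27e-05, adjusted p = 0.414 with an estimated correlation). Of these, 0 passed over all probe sets, and Cdh5 (0.60, SE 0.15), Kdr (0.58, SE 0.17) and Pecam1 (0.49, SE 0.15) passed adjusted over the list alone. Smooth muscle and pericyte genes rose by a mean of 0.40, with 7 of 9 higher (limma camera adjusted p = 0.00341, adjusted p = 0.414 with an estimated correlation). Again 0 passed over all probe sets, and the contractile genes Mylk (1.004, SE 0.25) and Acta2 (0.78, SE 0.20) and the pericyte marker Rgs5 (0.78, SE 0.20) passed adjusted over the list alone. The smooth muscle mean was 0.25 without mutant 1 and 0.63 without dim probe sets. Mutant 1 had both the highest fibroblast mean (11.00) and the highest adipocyte mean (12.42) of the 6 animals.

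Fat markers varied widely between animals of both groups. The adipocyte list had means of 8.78, 10.11 and 11.17 in controls and 12.42, 10.27 and 9.69 in mutants, and its mean change of 0.78, with 11 of 11 higher, did not pass (limma camera adjusted p = 0.0515). Ucp1, the uncoupling protein of brown fat, measured 7.27 ± 4.10 in controls and 9.01 ± 1.64 in mutants, and Adipoq 9.91 ± 2.37 and 11.40 ± 2.41 (SD, n = 3 each). Without mutant 1 the adipocyte change was -0.04, and it passed without control 3 (1.35), mutant 2 (1.04) or mutant 3 (1.33), and with quantile normalization, a shift to a common median or array weights. Kidney genes, which would mark attached kidney, had a mean change of 0.03 with 5 of 9 higher (limma camera adjusted p = 0.734), and 0 adipocyte or kidney genes passed adjusted over the list alone. Both group means of all 9 kidney genes lay within the background range.

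Chromaffin cell genes, which mark the adrenaline-producing medulla, were below controls for all 13 measured members and fell as a list (mean change -0.36, limma camera adjusted p = 0.00267, adjusted p = 0.533 with an estimated correlation). This rested on 1 animal: control 2 had a list mean of 13.53, the other controls 12.84 and 12.51, and the mutants 12.55 to 12.62. Without control 2 the change was -0.08 and the call was lost, and without control 3 it was -0.59. Single genes did not pass over all probe sets or adjusted over the list alone. Th, the rate-limiting enzyme of catecholamine synthesis, measured 16.13 ± 0.49 and 15.88 ± 0.17, and the neuropeptide gene Npy 13.67 ± 0.70 and 13.06 ± 0.38 (SD, n = 3 each). Schwann cell genes had a mean change of 0.07 and a median of -0.02 over 7 genes, all within the background range (limma camera adjusted p = 0.755), with 0 past adjusted over the list alone.

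Cell cycle genes rose by a mean of 0.36, with 17 of 19 higher (limma camera adjusted p = 0.000196, adjusted p = 0.414 with an estimated correlation), while 0 passed over all probe sets or adjusted over the list alone. Examples are the proliferation antigen Mki67 (log2 change 0.90, SE 0.34, and 0.53 without mutant 1), cyclin B2, Ccnb2 (0.70, SE 0.23), and the mitotic kinase Aurkb (0.47, SE 0.18). List means were 8.46, 8.46 and 8.51 in controls and 8.995, 8.95 and 8.56 in mutants. Chaperone and ER stress genes fell as a list, with log2 changes below 0 for 10 of 11 (mean -0.50, median -0.21, limma camera adjusted p = 0.00176, adjusted p = 0.439 with an estimated correlation). List means were 13.14, 13.35 and 12.765 in controls and 12.36, 12.61 and 12.80 in mutants, so mutant 3 lay above control 3. Over all probe sets 0 passed, and the lower members adjusted over the list alone were the inducible chaperones Hspa1a (-1.78, SE 0.50) and Hsph1 (-0.80, SE 0.23). At an unadjusted limma p under 0.05 there were 4 members, all heat shock genes, Dnajb1 (-0.73, SE 0.26) among them. ER stress genes were not among the 4, so the list's call does not show a fall of these. Immediate early genes, which respond within minutes to handling and stress, had a mean change of -0.05 over 12 genes (limma camera adjusted p = 0.755), with 0 past adjusted over the list alone.

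Immune lists moved in both directions, and 0 of their members passed over all probe sets. Interferon-stimulated genes fell, with log2 changes below 0 for 9 of 11 (mean -0.30, limma camera adjusted p = 0.0184, adjusted p = 0.533 with an estimated correlation). Irf7, a regulator of type I interferon, was the member past the threshold adjusted over the list alone (log2 change -1.31, SE 0.33), and Oasl2 had a log2 change of -0.56 (SE 0.17). The interferon call was lost without control 3 (mean -0.28), without mutant 3 (-0.14) and without dim probe sets (-0.32). Macrophage genes rose by a mean of 0.16, with 12 of 14 higher (limma camera adjusted p = 0.0419, adjusted p = 0.533 with an estimated correlation), Csf1r, the receptor for macrophage colony-stimulating factor, with a log2 change of 0.52 (SE 0.19) among them. Adjusted over the list alone 0 macrophage genes passed, and the call was lost without control 2 (mean 0.15), control 3 (0.15) or mutant 2 (0.04) and without dim probe sets (0.13). Antigen presentation genes (mean -0.39, 6 of 6 lower, limma camera adjusted p = 0.0515) and lymphocyte genes (mean 0.24, 9 of 11 higher, limma camera adjusted p = 0.0938) did not pass. Antigen presentation means were 10.16, 10.07 and 10.43 in controls and 10.35, 9.98 and 9.15 in mutants, and the change was -0.06 without mutant 3 and -0.65, past the threshold, without mutant 1. The lymphocyte list passed without mutant 3, at a mean of 0.31. Of its 11 genes, 9 lay within the background range in both groups, and the other 2, Cd3e and Cd4, in 1 group. H2-Ab1, of the class II complex, had a log2 change of -0.66 (SE 0.42, and -0.12 without mutant 3) and the T cell coreceptor Cd4 one of 0.77 (SE 0.36, and 0.35 without control 1). Neutrophil and mast cell genes did not pass either (mean -0.17, limma camera adjusted p = 0.322), and the mast cell protease Cpa3 alone passed adjusted over the list alone (-1.20, SE 0.25, mutant mean within the background range). Of the red blood cell list 2 members were measured, too few to test.

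**Figure D2:**
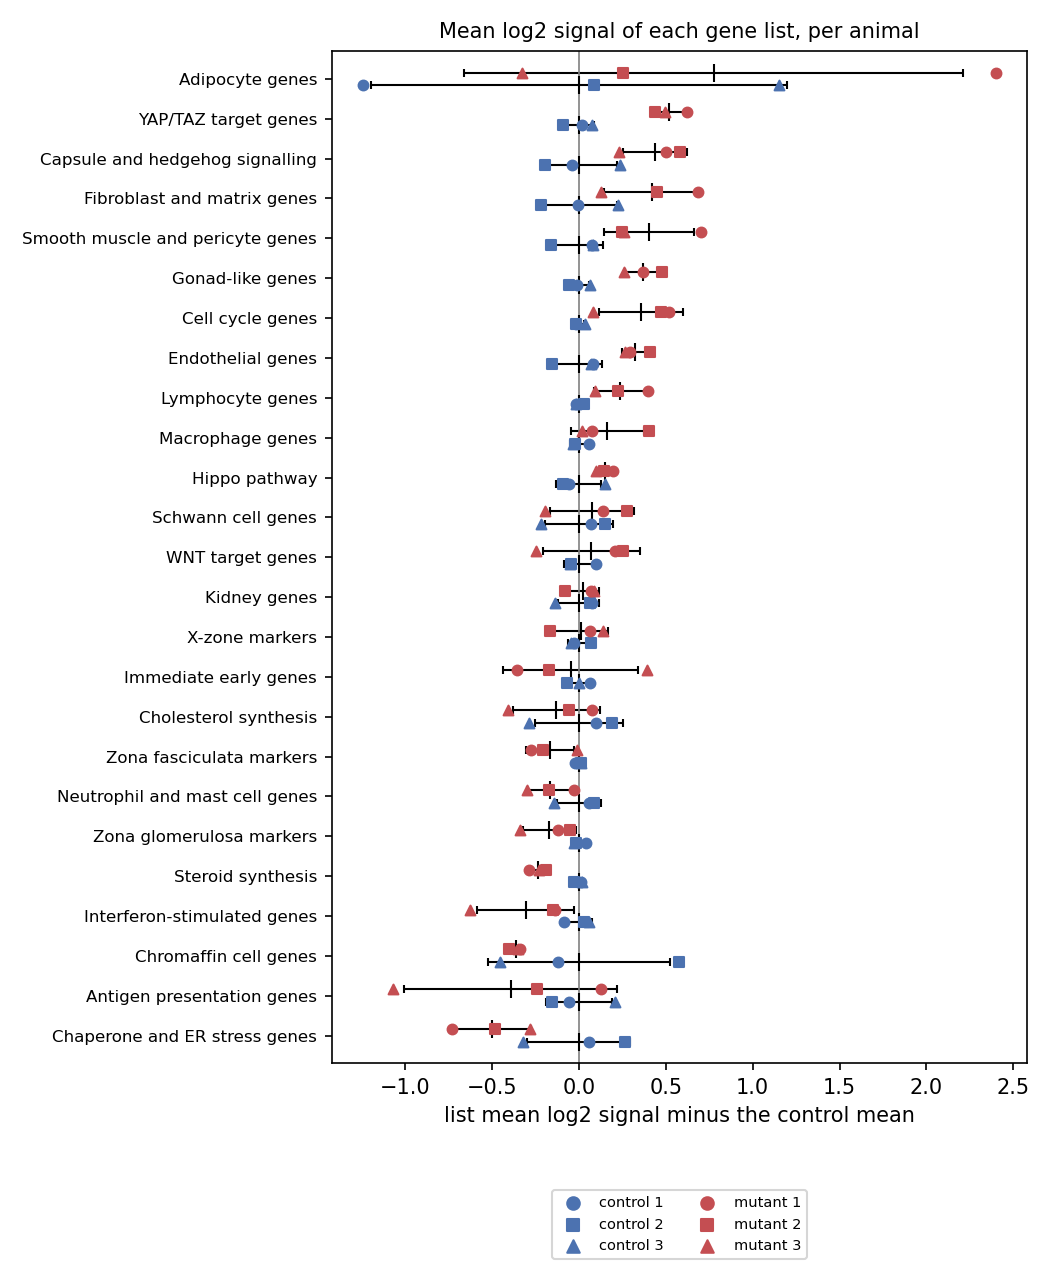
Mean log2 signal of the measured members of each of 25 gene lists, as each animal's value minus the control mean of that list (x axis, log2 units; 1 list per line, sorted by change), with controls in blue, mutants in red, a bar at each group mean and whiskers of 1 SD. All 3 mutants lie above all 3 controls for the YAP/TAZ target genes and for the gonad-like, smooth muscle, endothelial, lymphocyte and cell cycle genes. They lie below all 3 controls for the steroid synthesis, zona glomerulosa and interferon-stimulated genes. The adipocyte genes spread over the widest range in both groups.

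With camera's preset correlation 13 of the 25 lists passed, 9 higher and 4 lower. With an estimated correlation 0 passed, and 2 had an unadjusted p under 0.05. The fry test called 2 after adjustment, the YAP/TAZ target and steroid synthesis lists, and 4 at an unadjusted p under 0.05. By the exact two-sided permutation test of the list means, the YAP/TAZ target list had p = 0.1, the smallest that 3 animals against 3 can give. So did 8 others, and of these 9 lists 7 had passed camera and the zona glomerulosa and lymphocyte lists had not.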

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

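The intron control and adipocyte covariates were added after the data were seen; the other alternatives were planned. Esrp2 passed in 15 of 15 settings. The 16 called genes kept their direction in every setting tested, except that P4ha3 was removed by the filter on dim probe sets. In most settings this was fixed beforehand and is no sign of stability. Leaving out or weighting animals cannot turn the direction, because the groups did not overlap for any of the 16. Both filters on probe sets, the trend and robust variance and the replicate block leave the log2 change as it is. The rescalings could hardly turn a direction either, as array medians lay between 6.76 and 6.83 and the smallest called change was 1.21 (P4ha3). With the covariates the direction could have turned and did not. Signal over background limits the folds of genes with group means inside the background range of 2.53 to 7.32. The causes of the shifts below were not tested, also where a possible one is named.

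The count of 16 probe sets (12 higher, 4 lower) was 38 (27 and 11) with quantile normalization, 32 (20 and 12) with each array shifted to a common median, and 48 (33 and 15) with array weights. It was 175 (115 and 60) with a trend and robust variance. With fewer tests it was 92 (67 and 25) for probe sets above the median level, 41 (29 and 12) for those with 1 gene symbol and 41 (29 and 12) for the mean of a gene's probe sets, a setting that also averages probe sets. Looser thresholds gave 108 (82 and 26) at an adjusted p under 0.10 and 185 (124 and 61) at an unadjusted p under 0.05 with at least 2-fold. A covariate costs a degree of freedom, and the count was 8 (5 and 3) with the intron control level and 2 (1 and 1) with the adipocyte level. Of the 16 calls, 16 were shared with each of the quantile, median shift, symbol, trend and weight settings, 15 with the filter and 6 with the intron covariate. With 1 animal left out, and so fewer samples, the count ran from 1 to 15, with 1 to 12 higher and 0 to 3 lower: 1 without control 1, 2 or 3, 14 without mutant 1 (4 shared with the 16), 6 without mutant 2 (4 shared) and 15 without mutant 3 (8 shared).

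With the replicate number as a replicate block, the count was 1 (1 higher, 0 lower) and 12 lists passed, the call lost being that of the Hippo pathway list. The same-numbered animals of both groups did not deviate together: the correlations of their deviations from the group means were -0.09, 0.08 and -0.07 for numbers 1, 2 and 3. The values therefore show no pairing by number. What the numbers mark is not given in the sources used here.

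The count of 13 lists became 0 with an estimated correlation and 2 with fry, and lay between 10 and 16 in the other settings. Stk4 did not pass in any setting and its log2 change lay between -0.48 and -0.17. Reversed directions occurred among values that had not passed: Akr1c18 was 0.024 with quantile normalization, and with the adipocyte covariate Star was 0.0055 and the immediate early list 0.064. The camera test of the X-zone list turned from higher to lower with the intron covariate, at a mean of 0.0007. With 1 animal left out, mean changes ran from -0.053 to 0.099 for the X-zone list, -0.036 to 0.21 for Schwann cell, -0.037 to 1.35 for adipocyte, -0.043 to 0.079 for kidney, -0.27 to 0.11 for immediate early, -0.021 to 0.23 for WNT target and -0.27 to 0.0089 for cholesterol synthesis genes. Without turning sign they ran from -0.65 to -0.06 for antigen presentation genes, which passed in 8 of 18 settings, both rescalings among them, from -0.23 to -0.085 for zona glomerulosa markers, -0.24 to -0.11 for zona fasciculata markers, 0.16 to 0.31 for lymphocyte genes and -0.24 to -0.10 for neutrophil and mast cell genes. Single genes ran from -0.29 to 3.82 for Ucp1, -0.046 to 0.027 for Star, -0.49 to 0.0033 for Th, -0.047 to 0.016 for Akr1c18 and -0.016 to 0.35 for Ccn2. Of 67 genes named by the rule that had not passed, 21 moved by over 1.5 times with 1 animal left out.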

Other observations

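The test of medullary against stromal markers and the tests of matrix families were chosen after the results were seen, and the intron and adipocyte covariates were added after the data were seen. Further families of the extracellular matrix were higher in mutant glands, counted without members of the fixed fibroblast and matrix list. Microfibril genes rose by a mean of 0.49 over 13 genes, 12 of them higher (limma camera adjusted p = 0.000105), and laminins by 0.44 over 10 genes, 9 of them higher (limma camera adjusted p = 0.000188). With an estimated correlation both calls were lost (adjusted p = 0.184 each). Thrombospondins rose by 0.74 and lysyl oxidases by 0.57, over 3 genes each with 2 of them higher (limma camera adjusted p = 0.0228 for both, and adjusted p = 0.184 for both with an estimated correlation). With the 1 member each that the fixed list holds, the means were 0.59 for thrombospondins, 0.50 for lysyl oxidases and 0.44 for microfibril genes. Collagens had a mean change of 0.13 over 34 genes (limma camera adjusted p = 0.0944) and matrix metallopeptidases 0.17 over 21 genes (limma camera adjusted p = 0.0543), and neither passed. Adjustment was over 10 families, of which integrins (0.06, adjusted p = 0.107), serpins (0.10, adjusted p = 0.0987), secreted phospholipases A2 (-0.12, adjusted p = 0.507) and solute carriers (-0.03, adjusted p = 0.289) did not pass camera either.

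Single matrix genes, chosen after their values were seen, did not pass over all probe sets, although each separated the 3 mutants from the 3 controls. Mfap2 and Mfap4, microfibril-associated proteins, had log2 changes of 1.58 (SE 0.26) and 1.32 (SE 0.22), each with a limma adjusted p of 0.0795. Thrombospondin 1, Thbs1, had one of 1.58 (SE 0.24, limma adjusted p = 0.0629), and Loxl3, which crosslinks collagen and elastin, one of 1.17 (SE 0.18, limma adjusted p = 0.0621). The gelatinase Mmp2 had a log2 change of 1.36 (SE 0.25, limma adjusted p = 0.107). Hspg2, the basement membrane proteoglycan perlecan, which belongs to none of the families tested, had one of 0.98 (SE 0.17, limma adjusted p = 0.0803).

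Of the 10 ways to split the 6 animals into 3 and 3, 1, the real one, gave 16 or more probe sets, and the highest of the others gave 0. For gene lists with camera's preset correlation, 3 of the 10 splits gave 13 or more, the real 13 included, and the highest of the others gave 13. With 10 splits a share under 0.05 cannot be reached.

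The YAP/TAZ target list was fixed in advance, and its higher level in the mutants may reflect loss of the kinases that restrain YAP and TAZ, a hypothesis that the design names and that was not tested beyond the comparison itself. In the list mean 3 of 3 mutants lay above the highest control. These are the values that make up the rise itself, so they cannot tell whether an animal was mislabelled. RNA quality, only as far as the intron control signal reads it, and fat left on the gland are argued against as the whole cause. With each as a covariate, 96.0% and 93.6% of the mean change were left, at 0.50 (SE 0.05) and 0.49 (SE 0.07). Exon control signals, 10.79, 10.78 and 10.78 in the controls and 10.61, 10.78 and 10.73 in the mutants, were not used as a covariate. A larger share of stromal and vascular cells, whose marker lists were higher too, was not tested against this list and stays open, and the lost call with an estimated correlation leaves open how far the list stands apart from other genes.

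The higher fibroblast and matrix list could come from more stromal cells, from a lower share of cortical cells, or from fat and its stroma left on the gland. A lower cortical share would raise chromaffin markers as well, but the fibroblast change exceeded the chromaffin change by 0.785 (SE 0.457), within 2 SE of 0, with 2 of 3 mutants above the highest control, so this cannot be told apart. With the adipocyte level as a covariate 74.1% of the fibroblast change was left (0.31, SE 0.17), and with the intron control level 91.6% (0.39, SE 0.21). Both remainders lie within 2 SE of 0, because fibroblast levels differ among animals of a group, so neither explanation is excluded. The genotype stays open as well.

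The matrix families could owe their mean change to a few genes. Of the 84 matrix genes, with a mean change of 0.27, 4 were past an adjusted p of 0.10. Without these 4, the mean of the other 80 exceeded that of all other genes by 0.213 (SE 0.041 over genes). The families were picked for their change and their genes vary together, so this SE is too small, and a change of a few genes and one of the families cannot be told apart.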
